A study of Homo sapiens with 5 samples.

How the data were processed

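RNA of 231-BM cells was measured in 5 samples, each on a 2-colour Agilent array of 44495 features, 43118 of them probes of transcripts, that stand for 34127 distinct probes. Per the labels, RNA of untreated cells carried Cy3 and RNA of cells given OSM for 4 hours carried Cy5 on every array, so the dyes were not swapped. The groups are control shRNA (1 array), Lnc-BM shRNA (2 arrays, hairpins 1 and 2), JAK2 WT (1 array) and JAK2 KO (1 array). Per the file headers, the arrays lie on 3 slides and were scanned in 2 sessions: slide 1 holds control shRNA and JAK2 WT, slide 2 holds hairpin 1 and JAK2 KO, and slide 3, alone in session 2, holds hairpin 2.

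The deposited scanner files hold intensity values: the mean pixel brightness of each spot in each dye and the median brightness of its local background, as made by Agilent Feature Extraction 11.5.1.1 in session 1 and 11.0.1.1 in session 2, per the file headers. The same deposited files hold processed intensities, from which the scanner software had subtracted background and which it had dye-normalized, and a log10 ratio of Cy5 over Cy3 made from these, per the file headers. They also hold the scanner software's p-value that this ratio is 0 within an array, per the file headers. The authors' value table gives a ratio per feature whose scale is not stated. Set against the same array's log10 ratio over 43118 features, each column had a slope of 1.00 and a correlation of 1.00, and each column's median was 0. The value table is therefore on the log10 scale of Cy5 over Cy3 with the scanner's own centring, and neither scale, centring nor direction stays unknown.

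Median Cy3 and Cy5 brightness was 168 and 96.7 with control shRNA, 158 and 100 with hairpin 1, 115 and 168 with hairpin 2, 150 and 104 in JAK2 WT and 161 and 117 in JAK2 KO. The scanner software marked 63.1 and 69.6 percent of probe features well above background in Cy3 and Cy5 with control shRNA, 66.3 and 68.4 with hairpin 1, 57.4 and 59.7 with hairpin 2, 64.9 and 72.4 in JAK2 WT, and 64.8 and 73.6 in JAK2 KO. Local Cy5 background was 58.0 with hairpin 2 and 19.0 to 19.5 elsewhere. Probes printed 10 times had a median spread (standard deviation) of their log2 ratio of 0.0259, 0.0284, 0.0551, 0.0269 and 0.0311 on the arrays in the order of the labels, and 0 probe spots were saturated. At the scanner's own p-value under 0.01, 984 features were higher and 664 lower with control shRNA, 362 and 482 with hairpin 1, 1068 and 305 with hairpin 2, 1082 and 786 in JAK2 WT, and 247 and 200 in JAK2 KO.

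Values were computed in R 4.3.3 with limma 3.58.1, and tables and figures in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Mean spot signals were corrected by the normexp method with an offset of 50, each array's log2 ratios were normalized by loess, and channel levels were made comparable between arrays by quantile normalization of mean intensities (Aquantile). While the files were examined, 39 spots with a local background over 3 times their array's median (4 with control shRNA, 14 with hairpin 1, 21 in JAK2 WT) were found to distort the background model. They were left out of that model, a choice made after seeing the data, and the fit with all spots is among the alternatives. Repeated spots of a probe were averaged. A probe was tested if it was well above background in either dye on at least 2 of 5 arrays; 23767 probes passed, 178 of which had no value on an array. Each gene is represented by its probe with the highest mean intensity, chosen over all arrays, which left 18212 genes or transcripts (15275 with a gene name, 2937 with only a clone or accession). Probe names were brought up to date with a RefSeq table of assembly GRCh38.p14, used for names only: 26377 probes by accession, 2223 by symbol, 342 by synonym, and 5185 kept the file's name. Coordinates are those of the hg19 annotation of the hairpin 2 file; the other files carry hg18.

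Each result was tested in limma (lmFit and eBayes without trend) with a coefficient for each of the 4 groups, on the log2 ratios for the OSM response and on the log2 levels of a single dye for levels without (Cy3) and with (Cy5) OSM. The p-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. The residual spread comes from the hairpin pair alone (1 residual degree of freedom, with 4.36 prior degrees for ratios and 3.01 and 2.97 for levels). Groups of 1 array are assumed to vary like that pair. The median standard error of a log2 difference was 0.0703 for the OSM response in the controls, 0.122 for Lnc-BM, 0.141 for JAK2 and 0.186 for the difference between these effects, and for levels without OSM 0.419 for Lnc-BM and 0.484 for JAK2. Counts by size use a ratio or difference of at least 2-fold, for Lnc-BM in the same direction with both hairpins. The share of the OSM response kept was added after the data were examined: the median, over genes at 2-fold or more on the control array not used as the reference, of the perturbed array's log2 ratio in percent of its control's.

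A set of 21 gene lists with 557 distinct members was fixed before the data were examined. They are JAK-STAT3 targets and feedback, OSM receptor and JAK-STAT components, acute phase proteins, chemokines and cytokines, adhesion molecules, interferon-stimulated genes, NF-kB targets, immediate early and MAPK feedback genes, EMT and matrix remodelling, hypoxia and glycolysis, cell cycle and proliferation, p53 targets, unfolded protein response, cholesterol synthesis, apoptosis regulators, cytosolic ribosomal proteins, and markers of haematopoietic, endothelial, neural and glial, luminal epithelial, and fibroblast and basal cells. The lists overlap: 15 NF-kB targets, 12 JAK-STAT3 targets and 11 chemokines and cytokines are also in another list. Their results are therefore not independent of each other. The median of each list was set against 10000 random lists of the same size matched in 10 bins of intensity. The genes named were also fixed by rule beforehand. They are the 10 highest and 10 lowest of each comparison, ranked by the smaller of the differences where there are 2 arrays, and up to 4 members of a list with the largest change. JAK2, Lnc-BM, OSMR, IL6ST, LIFR, STAT3, SOCS3, ICAM1, CCL2 and VCAM1 are named in every comparison where measured. Others were chosen after their values were seen: EGR1 for JAK2 KO, MALAT1 on the JAK2 KO array, and the genes of the closing part. Genes near background on all arrays of a group get a bound on their fold, taken from the dim side's level, and no fold where both sides are dim.

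Alternatives planned beforehand were the scanner's processed signals, no background correction, an offset of 16, median centring for loess, other filters, the mean of all probes of a gene, the authors' value table, pooled control arrays, a variance trend, scan session as a block, other normalization between arrays, a 1.5-fold size, and leaving out each hairpin with pooled controls. Not run were a joint fit of both dyes and slide as a random block, since neither correlation could be estimated. Lnc-BM itself, with 0 probes of that name, and genes that passed no filter were left out. The fit was tested on simulated data with 200 of 18212 genes changed by a log2 difference of 1, 2 or 3. It recovered 198, 200 and 200 for the OSM response in the controls (20, 21 and 30 false calls), 0, 194 and 200 for Lnc-BM (0, 6 and 20 false calls) and 0, 197 and 200 for JAK2 (0, 9 and 16 false calls). The simulated variances follow the distribution limma itself fits. A first simulation, drawn from the moderated variances, gave more false calls and was replaced after its result was seen. The recovered and false calls therefore hold only under that assumption. The simulated noise was independent between arrays, with no slide or session difference, and all 200 genes changed by the same size. The recovered counts therefore do not measure the power of the real comparisons.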

Results

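The series measured messenger RNA in 231-BM cells, a brain-metastatic derivative of the breast cancer line MDA-MB-231, with and without Oncostatin M (OSM). OSM is a cytokine of the interleukin 6 family that signals through a receptor holding IL6ST and OSMR to JAK kinases and STAT3. Each of the 5 samples is a 2-colour array. RNA of untreated cells carried the green dye Cy3 and RNA of cells given OSM for 4 hours the red dye Cy5, so each array gives an OSM ratio of its own. The arrays hold cells with a control short hairpin RNA (shRNA, a construct that silences a chosen transcript; 1 array), with either of 2 hairpins against the long non-coding RNA Lnc-BM (1 array each), with intact JAK2 (JAK2 WT, 1 array) and with JAK2 knocked out (JAK2 KO, 1 array). The number of arrays limits the precision of every value, and 18212 genes or transcripts were bright enough to test. Control shRNA and JAK2 WT lay on slide 1, hairpin 1 and JAK2 KO on slide 2, and hairpin 2 on slide 3, which was scanned in another session. No slide held a perturbed array together with its control, so slide and perturbation are not separable here. Nothing in the labels says that the samples came from separate cultures, so every p below measures only the spread between these arrays.

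The knocked-out gene itself comes before the comparisons. JAK2 was read by a single probe (chromosome 9, 5127355 to 5127414, build hg19), with a log2 level without OSM of 7.94 on the JAK2 WT array and 7.91 on the JAK2 KO array. The other levels of JAK2 were 7.75 with control shRNA, 7.91 with hairpin 1 and 7.77 with hairpin 2. The labels do not say which part of JAK2 was deleted, and a probe outside the deleted part checks nothing. No probe carries the name Lnc-BM, so its level, and with it the knockdown, was not analysed here.

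The first question is which genes OSM moved within 4 hours in cells with intact JAK2 and Lnc-BM, taken as the mean of control shRNA and JAK2 WT. SERPINB3 and SERPINB4, which encode protease inhibitors, rose most. NNMT (nicotinamide N-methyltransferase), the angiotensin precursor AGT, the acute phase protein SAA2, PTGS2 (cyclooxygenase 2), the signalling inhibitor SOCS3 and the cytokine IL6 rose as well. LFNG, which encodes an enzyme that modifies Notch receptors, fell most, and the growth factor PGF and the chemokine receptor CXCR4 fell. JAK2, STAT3 and OSMR, parts of the pathway that OSM itself uses, rose.

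In limma, SERPINB3 rose by a log2 ratio of 6.67 (102-fold, adjusted p = 0.0115), SERPINB4 by 6.40 (84.2-fold, adjusted p = 0.00832) and NNMT by 3.66 (12.7-fold, adjusted p = 0.00121), each on both control arrays. SAA2 rose by 3.14, AGT by 3.11, TNIP3 by 2.94, PTGS2 by 2.91, SOCS3 by 2.80, IL6 by 2.43 and LRG1 by 2.34. SOCS3 stood at 2.78 with control shRNA and 2.83 in JAK2 WT, and PTGS2 at 2.88 and 2.94. On the falling side LFNG reached a log2 ratio of -2.30, PGF -1.65, DHRS3 -1.51, ADRA1B -1.42, BHLHE41 -1.37, CABLES1 -1.34 and CXCR4 -1.29. UBE2E1 fell too, at -1.51 with control shRNA and -1.48 in JAK2 WT. ASB2 at -1.75 (limma adjusted p = 0.0786) and IL11 at -1.43 (limma adjusted p = 0.0982) lay as far below 0 on both arrays without passing the test. CCL2 rose by 2.25, JAK2 by 1.23, ICAM1 by 1.22, STAT3 by 0.73 and OSMR by 0.70, while IL6ST at 0.36 (limma adjusted p = 0.146) and LIFR at 0.21 (limma adjusted p = 0.175) did not pass. VCAM1 was not above background on any array. Probes of the same gene do not always read alike: they ranged from 0.74 to 3.14 for SAA2, from 0.23 to 2.43 for IL6 and from -2.30 to -0.40 for LFNG.

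Of 29 JAK-STAT3 targets and feedback genes measured, 14 rose, none fell and 15 did not pass the test, with SOCS3, SOCS1 (2.13), BCL3 (1.81) and CEBPD (1.48) at the front. Adjusted over the list alone, 21 rose and 1 fell. Interferon-stimulated genes rose in 13 of 38 cases (21 rose and 1 fell adjusted over the list alone), with GBP1 at 1.69, TAP1 at 1.27 and IRF9 at 1.18. NF-kB targets rose in 11 of 30 and fell in 2 (15 and 3 adjusted over the list alone), among them PTGS2, IL6 and CXCL3 (1.69). Chemokines and cytokines rose in 8 of 25 (10 rose and 2 fell adjusted over the list alone), with IL6, CCL2, CXCL3 and CXCL5 (1.65). IL6 and CXCL3 are counted in both of these lists. Acute phase proteins rose in 7 of 18 (8 adjusted over the list alone), including SAA2, SAA1 (2.26), SERPINA1 (1.03) and the complement factor CFB (0.83). Of 25 OSM receptor and JAK-STAT components, 5 rose and 1 fell, and the counts were the same adjusted over the list alone. Medians of these lists were 0.44, 0.27, 0.30, 0.17, 0.18 and 0.14, each above all or nearly all of 10000 random lists of like intensity.

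Of 49 cytosolic ribosomal protein genes 8 rose, 28 adjusted over the list alone, and 42 lay above 0, with a median of 0.29, RPL23 at 0.72 and RPLP0 at 0.62. The list median was alike on the perturbed arrays, at 0.26 with hairpin 1, 0.27 with hairpin 2 and 0.30 in JAK2 KO. Without a dye swap, OSM and a fixed dye bias cannot be told apart for this list. Immediate early and MAPK feedback genes split, with 7 of 35 risen and 1 fallen (7 and 2 adjusted over the list alone). EGR1 rose by 1.51, JUNB by 1.41, FOS by 1.18 and ATF3 by 0.90, yet the list median was -0.06 while its mean was 0.11. Probes of ATF3 ranged from -0.06 to 0.90. In the EMT and matrix remodelling list 6 of 31 rose and 2 fell (10 and 3 adjusted over the list alone), with THBS1 at 1.09, SERPINE2 at 0.95, TIMP3 at -1.28 and the protease PLAU at -1.16. Hypoxia and glycolysis genes rose in 2 of 30 (6 rose and 3 fell adjusted over the list alone), the glucose transporter SLC2A3 by 1.56 and VEGFA by 1.03. Adhesion molecules rose in 4 of 24 and fell in 1 (the same adjusted over the list alone), with ITGB3 (1.49 with control shRNA, 1.51 in JAK2 WT), ICAM1, CEACAM1 at 0.66 and CD44 at 0.49. The adhesion median was -0.07 and its mean 0.04. Luminal epithelial markers fell in 4 of 20 (1 rose and 5 fell adjusted over the list alone), CLDN4 by -1.08, AGR2 by -0.71 and KRT19 by -0.55.

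Few members of the other lists passed the test. Unfolded protein response genes rose in 3 of 23 (CALR 0.50), apoptosis regulators in 3 of 32 (CASP8 0.77), and p53 targets rose in 1 of 25 and fell in 1 (GADD45A 0.58). Adjusted over the list alone these counts were 3 risen, then 5 risen and 2 fallen, then 2 risen and 4 fallen. In the p53 list the median was 0.00 and the mean -0.01. Of 40 cell cycle and proliferation genes 1 fell, CDC25A by -0.43, also adjusted over the list alone. None of 24 cholesterol synthesis genes passed, by either adjustment, and their median was -0.00 with a mean of 0.04. Markers of haematopoietic, endothelial, neural and glial, and fibroblast and basal cells moved in 1 or 2 members of a list. These were CD14 (0.84) of 16 haematopoietic, KDR (0.51) of 10 endothelial, TUBB3 (0.72) and 1 other of 11 neural and glial, and PDGFRA (1.53) and KRT17 (0.83) of 11 fibroblast and basal markers. Adjusted over the list alone they were 1, 1, 2 and, for fibroblast and basal markers, 3 risen and 2 fallen. The haematopoietic list had a median of -0.02 and a mean of 0.05.

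The limma test of this mean against 0 called 838 of 18212 genes, 513 higher and 325 lower, at an adjusted p under 0.05. By size, 112 genes were at least 2-fold higher and 31 lower with control shRNA, and 102 and 33 in JAK2 WT. The lists of these arrays shared 98 higher and 29 lower genes, against 0.627 and 0.0562 if they were independent. With the scanner software's processed signals limma called 0 genes, against 2957 at an unadjusted p under 0.05. No call therefore held under that processing, and the rises and falls above are those of the main fit. With every ratio centred on its array's median in place of the loess curve the calls were 248 higher and 317 lower. They were 146 and 21 with an offset of 16, and 1282 and 1269 with pooled controls. The dyes were not swapped on any array, so a probe's own dye bias is part of each ratio against 0, and the spread comes from the hairpin pair alone, on the assumption that the single arrays vary alike.

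**Figure D1:**
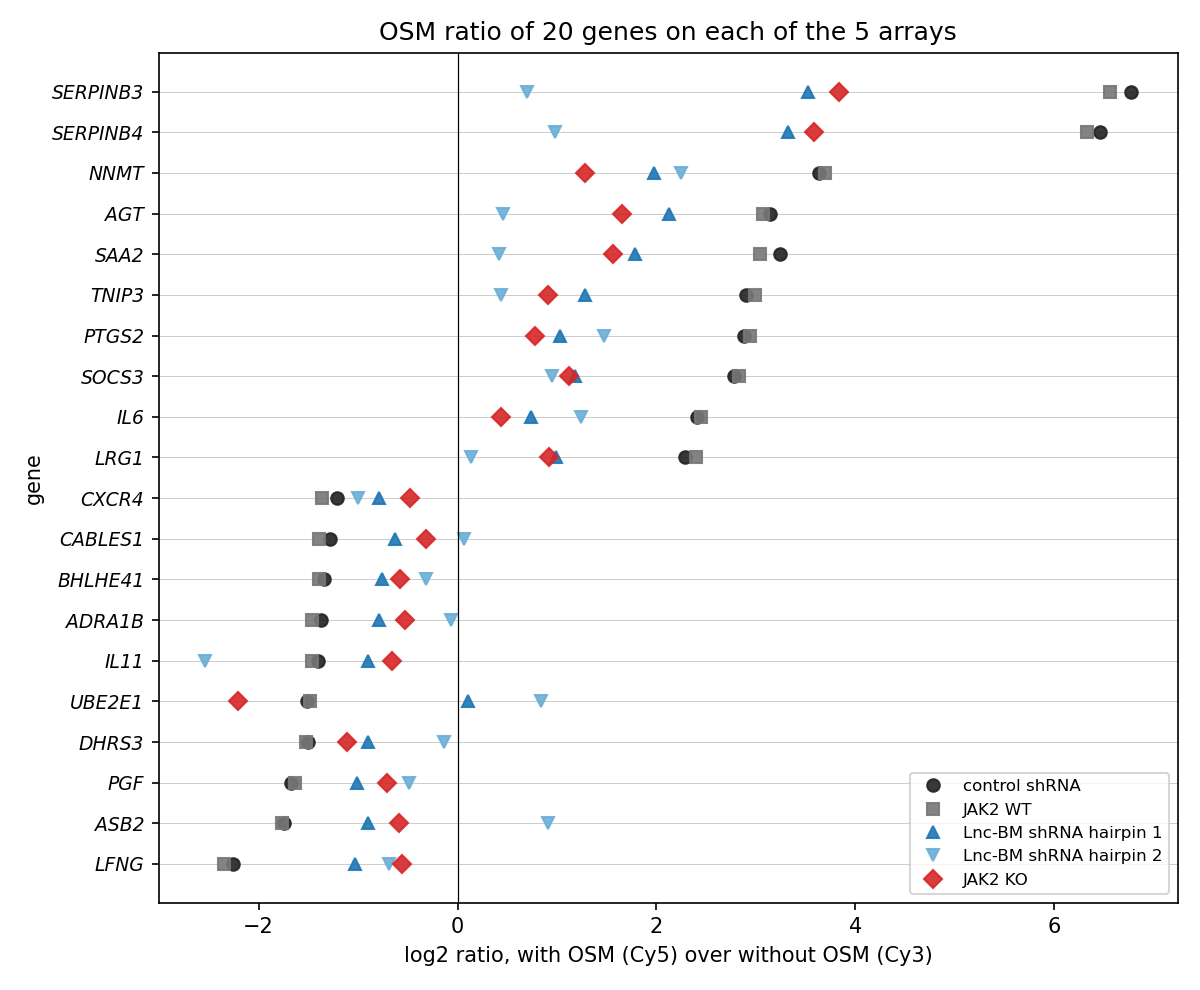
Log2 OSM ratio of the 10 genes with the highest and the 10 with the lowest ratios in both control arrays, shown on each of the 5 arrays.

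The next comparison asks how the OSM response changes without JAK2. Most of the genes that OSM moved far in JAK2 WT cells moved less in JAK2 KO cells, in both directions, but UBE2E1 moved further (-2.21 against -1.48). SERPINB3, SERPINB4, NNMT, PTGS2, IL6 and SOCS3 had lower ratios, as had the chemokine CXCL3, the interferon-induced GTPase GBP1, the BMP antagonist NOG and the NF-kB inhibitor TNIP3. LFNG, NANOS1 and the lipid transporter SPNS2, which lay below 0 in JAK2 WT, lay nearer to 0 in JAK2 KO.

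SERPINB4 was lower by a log2 difference of -2.75 (3.58 in JAK2 KO against 6.33 in JAK2 WT), SERPINB3 by -2.72 (3.83 against 6.56) and NNMT by -2.41 (1.28 against 3.69, limma adjusted p = 0.442). PTGS2 differed by -2.17, TNIP3 by -2.09, NOG by -2.06, IL6 by -2.01, SOCS3 by -1.71, CXCL3 by -1.68 and GBP1 by -1.55. The ratio of ICAM1 was 0.08 in JAK2 KO against 1.32 in JAK2 WT, and that of CCL2 0.91 against 2.21. The untreated levels of CXCL3, CXCL2 and CCL2 were higher in JAK2 KO (by 1.89, 1.26 and 1.16), and their levels with OSM differed by 0.22, 0.24 and -0.13. IL6 was likewise 1.23 higher untreated and -0.78 with OSM, LFNG -1.27 and 0.52, and PGF -0.94 and -0.01. Without hairpin 2 and with pooled controls, ICAM1 differed by 0.75 untreated and -0.38 with OSM. For CXCL3, CXCL2, CCL2 and PGF nearly all of the change in ratio therefore lies in the untreated cells. With OSM their levels were near those of JAK2 WT. For IL6, LFNG and ICAM1 part of the change lies in the untreated cells. JAK2 differed by -0.89, STAT3 by -0.82, OSMR by -0.61, LIFR by -0.14 and IL6ST by 0.04. In the other direction LFNG differed by 1.79 (-0.56 against -2.35), NANOS1 by 1.31, ASB2, FAM43A and SPNS2 by 1.18 each, EDN1 by 1.12, CABLES1 by 1.07, MAMLD1 by 0.96, ADRA1B by 0.93 and PGF by 0.93.

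No list member passed the test over all genes. Interferon-stimulated genes were lower in 37 of 38 members (median -0.34), 11 of them fallen adjusted over the list alone, GBP1, TAP1 (-1.19) and GBP4 (-0.93) among the lower ones. JAK-STAT3 targets were lower in 25 of 29 (median -0.34, 5 fallen adjusted over the list alone), among them SOCS3, SOCS1 (-1.17), BCL3 (-1.12) and CEBPD (-1.02). NF-kB targets had a median of -0.13 with 7 fallen adjusted over the list alone, and chemokines and cytokines -0.17 with 6 (CXCL2 -1.02). OSM receptor and JAK-STAT components had a median of -0.13 with 4 fallen, and hypoxia and glycolysis genes, lower in 27 of 30, -0.21 with 1 (SLC2A3 -1.13), again adjusted over the list alone. Acute phase proteins had a median of -0.26 (SAA2 -1.48, SAA1 -1.39) and unfolded protein response genes -0.15, with none past either adjustment. The adhesion list had a median of 0.00 and a mean of -0.08, with 2 fallen adjusted over the list alone (ICAM1 -1.24, ITGB3 -1.14). Immediate early genes had a median of -0.09 and none passed, JUNB at -0.89 and EGR1 at -0.16 (1.35 in JAK2 KO against 1.52 in JAK2 WT).

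In limma 0 genes passed, the smallest adjusted p being 0.442, and 712 had an unadjusted p under 0.05. By size, 7 genes had an OSM ratio at least 2-fold higher and 48 at least 2-fold lower in JAK2 KO. Among the 143 genes at 2-fold or more with control shRNA, JAK2 KO kept a median of 34.7 percent of the JAK2 WT log2 ratio, with quartiles at 23.7 and 45.8 percent. Without hairpin 2 and with both control arrays as 1 group, limma called 656 genes, 238 higher and 418 lower, with SOCS3 at -1.69 (adjusted p = 2.0e-07) on the JAK2 KO array. The spread of that fit is the difference between the control arrays of slide 1 alone, which holds nothing of the spread between slides.

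**Figure D2:**
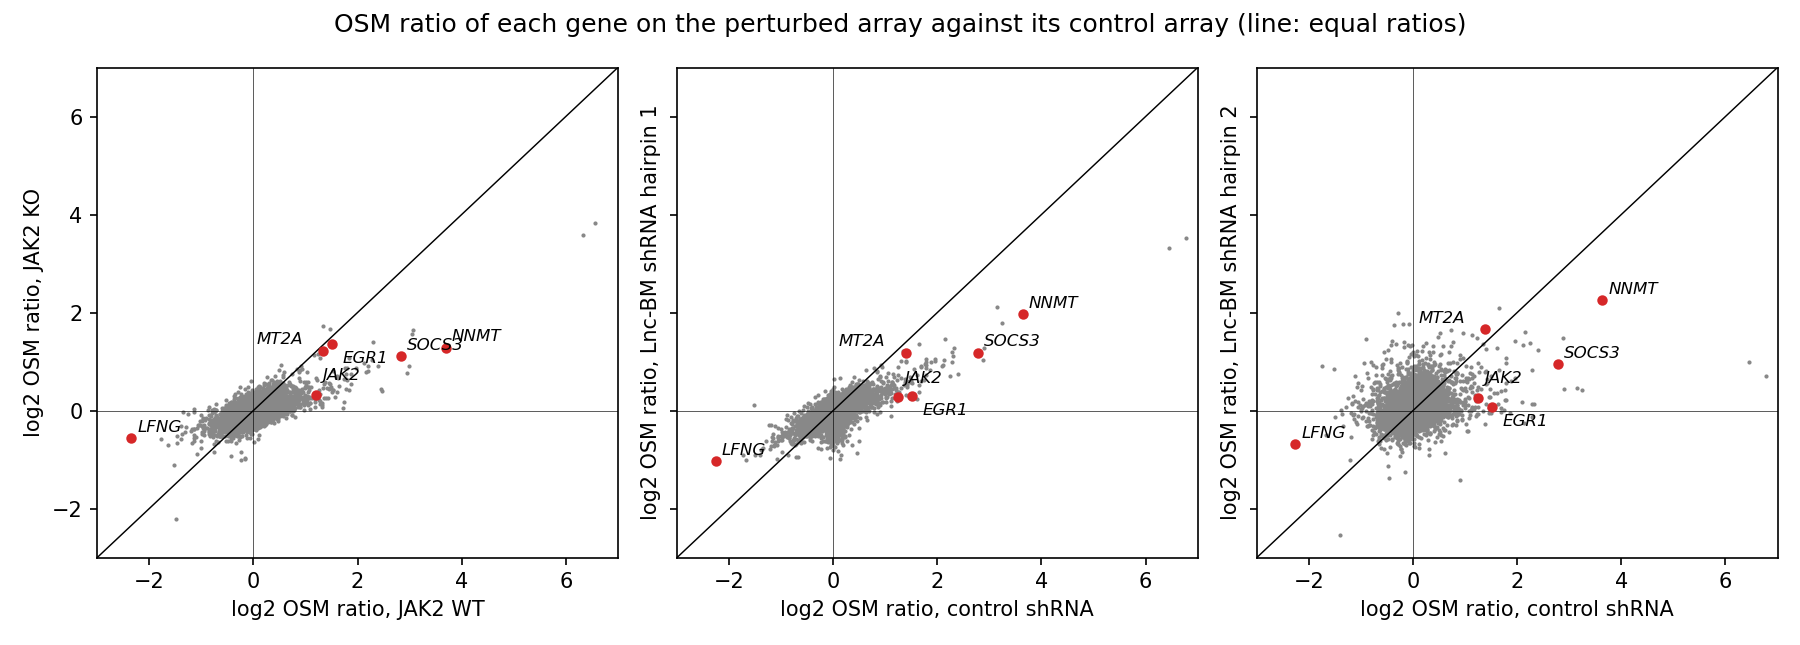
OSM ratio of every tested gene on each perturbed array against its control array, with 6 genes marked. Points on the line have equal ratios, and the marked genes were chosen after the values were seen.

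The same question was asked for Lnc-BM, with both hairpins set against control shRNA. The OSM ratios of SERPINB3, SERPINB4, SAA2, TNIP3, LRG1, SOCS3, PTGS2 and NNMT were lower with each hairpin, as were those of the interferon-induced genes GBP1 and APOL6. LFNG, NANOS1, SPNS2 and the receptor gene ROR1, which lay below 0 with control shRNA, lay nearer to 0 or above it. UBE2E1, which encodes a ubiquitin-conjugating enzyme, and the long non-coding RNA MALAT1 lay below 0 with control shRNA and higher with both hairpins. These higher ratios come with lower untreated levels with both hairpins. Without hairpin 2 and with pooled controls, MALAT1 with hairpin 1 differed by -1.46 untreated and by -0.60 with OSM.

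SERPINB3 differed by -4.66 (3.53 with hairpin 1 and 0.70 with hairpin 2 against 6.77 with control shRNA) and SERPINB4 by -4.31. SAA2 differed by -2.14, TNIP3 by -2.04, LRG1 by -1.73, SOCS3 by -1.71 (1.18 and 0.95 against 2.78, limma adjusted p = 0.421), PTGS2 by -1.63, NNMT by -1.52, GBP1 by -1.39 and APOL6 by -1.32. CCL2 differed by -1.32, JAK2 by -0.99 (0.27 and 0.26 against 1.25), STAT3 by -0.41, ICAM1 by -0.40, OSMR by -0.31, LIFR by -0.18 and IL6ST by -0.02. UBE2E1 differed by 1.99, ASB2 by 1.74, MYEOV by 1.55, LFNG by 1.40, ROR1 by 1.23, MALAT1 by 1.22, PRICKLE1 by 1.16, SPNS2 by 1.05, and NANOS1 and GPR39 by 1.01 each. Hairpin 2 carries much of several means: with hairpins 1 and 2 ASB2 stood at 0.84 and 2.65, MYEOV at 0.74 and 2.36, ROR1 at 0.79 and 1.66, PRICKLE1 at 0.71 and 1.62, GPR39 at 0.69 and 1.33, and SAA2 at -1.46 and -2.82.

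JAK-STAT3 targets were lower in 25 of 29 members (median -0.29), with 4 fallen adjusted over the list alone, SOCS1 (-1.74) and BCL3 (-1.18) among the lowest. Interferon-stimulated genes were lower in 33 of 38 (median -0.17, 12 fallen adjusted over the list alone), with GBP1, TAP1 (-1.12) and GBP4 (-0.90). NF-kB targets had a median of -0.17 with 7 fallen, acute phase proteins -0.11 with 3 (SAA1 -1.61), and chemokines and cytokines -0.06 with 5 (IL6 -1.41, CCL20 -1.23, CXCL5 -1.20), all adjusted over the list alone. OSM receptor and JAK-STAT components had a median of -0.02 with 3 fallen, hypoxia and glycolysis genes -0.06 with 2, and immediate early genes -0.05 with 2 by the same adjustment (DUSP1 -1.54, EGR1 -1.33, JUNB -1.23). With hairpins 1 and 2 apart, DUSP1 stood at -0.78 and -2.31, JUNB at -0.80 and -1.66, SAA1 at -1.03 and -2.18, SOCS1 at -1.11 and -2.38, and CXCL5 at -0.77 and -1.63. Adhesion molecules had a median of 0.02 with 2 fallen adjusted over the list alone (ITGB3 -1.06, but 0.03 with all spots in the background model). Cell cycle genes were slightly higher in 35 of 40 (median 0.12) and cholesterol synthesis genes lower in 20 of 24 (median -0.14), none past either adjustment. The p53 list had a median of 0.00 and a mean of -0.02, with CDKN1A at -0.84, and the fibroblast and basal list a median of 0.06 and a mean of -0.13.

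In limma 0 genes passed, the smallest adjusted p being 0.421, and 699 had an unadjusted p under 0.05. By size, 2 genes were at least 2-fold higher and 27 at least 2-fold lower with both hairpins, while hairpin 1 alone had 2 and 36 and hairpin 2 alone 116 and 79. Among the 135 genes at 2-fold or more in JAK2 WT, hairpin 1 kept a median of 46.8 percent of the control shRNA ratio and hairpin 2 kept 15.5 percent. The hairpin 2 share was 6.18 percent with the authors' table, 26.5 with all spots in the background model and 42.0 over bright genes alone. Without hairpin 2 and with pooled controls, SOCS3 differed by -1.62 on the single hairpin 1 array. The spread of that fit is again that between the control arrays of slide 1 alone. With median centring in place of loess, the medians of the interferon and NF-kB lists turned to 0.07 and 0.04. Those of the immediate early, EMT, hypoxia and cholesterol lists turned further, to 0.24, 0.21, 0.21 and 0.18.

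The Lnc-BM and JAK2 effects on the OSM response were then set side by side. They overlapped in SERPINB3, NNMT, SOCS3 and LFNG. Of 27 genes lower by 2-fold with both hairpins and 48 in JAK2 KO, 23 were the same, against 0.0712 if the lists were independent. Across all genes the effects correlated at r = 0.485 (rho 0.206), with r = 0.444 for hairpin 1 and 0.435 for hairpin 2, and at 0.292 with processed signals, 0.289 with the authors' table and 0.317 with all spots in the background model. The controls share slide 1, and hairpin 1 and JAK2 KO share slide 2. Whether that adds to the overlap was not tested. Hairpin 2, on slide 3, shares no slide with JAK2 KO. A ratio can fall 2-fold mainly where OSM had raised it, and 98 genes were at least 2-fold higher on both control arrays. Any loss of response on both sides would give a large overlap and a positive correlation, so independence is a weak yardstick here. EGR1, which encodes an early response transcription factor, kept its ratio in JAK2 KO (1.35) and not with hairpin 1 (0.29) or hairpin 2 (0.07). The ratio of UBE2E1 moved in opposite directions. In the limma test of the difference between the effects 0 genes passed, the smallest adjusted p being 1.00, and 210 had an unadjusted p under 0.05. Without hairpin 2 and with pooled controls the difference was -1.06 for EGR1 and 2.32 for UBE2E1. The spread of that fit is that between the control arrays of slide 1 alone.

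Cells that had not seen OSM were compared next, to ask what the loss of JAK2 changes beforehand. The JAK2 KO array had less OSMR, the receptor chain of OSM, and less of the aldehyde dehydrogenase gene ALDH3A1, the calcium-binding protein gene S100P, the integrin chain ITGB4 and the chemerin receptor CMKLR1. It had more of the chemokines CXCL3 and CXCL8, the cytokines IL32 and IL1A, and the heat shock gene HSPA6.

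OSMR was lower by -1.75 (6.95 in JAK2 KO against 8.71 in JAK2 WT, limma adjusted p = 1.00), ALDH3A1 by -2.63, CMKLR1 by -2.44, S100P by -2.34, ITGB4 by -1.96, PLSCR4 by -1.94, APOBEC3G by -1.80, HAPLN2 by -1.75, and SLCO4A1-AS1 and LOXL4 by -1.61 each. HSPA6 was higher by 2.35, CXCL3 by 1.89, KRTAP2-3 by 1.62, CXCL8 by 1.51, DHRS3 2.84-fold, IL32 2.83-fold, TTC33 by 1.49 and IL1A by 1.47. CD300LG and CDC42BPG were not above background in JAK2 WT and were at least 3.13-fold and at least 2.87-fold higher in JAK2 KO. CCL2 was higher by 1.16, ICAM1 by 0.80, STAT3 by 0.48, SOCS3 by 0.13 and LIFR by 0.05, and JAK2 was lower by -0.04 and IL6ST by -0.08. Probes of 1 gene ranged from 0.51 to 2.35 for HSPA6 and from -2.44 to -0.68 for CMKLR1.

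Chemokines and cytokines were higher in 19 of 25 members (median 0.40), 8 of them by 2-fold or more, with CXCL3, CXCL8, IL32 and IL1A in front. Unfolded protein response genes were higher in 20 of 23 (median 0.31), SDF2L1 by 1.00, DDIT3 by 0.82 and HERPUD1 by 0.63. Interferon-stimulated genes were higher in 30 of 38 (median 0.15, HLA-B 0.94) and NF-kB targets in 20 of 30 (median 0.12, CXCL2 1.26). JAK-STAT3 targets had a median of -0.11 (ETV6 -1.04), adhesion molecules -0.14 (ITGAV -0.86) and EMT and matrix remodelling genes -0.10 (COL6A1 -1.35, SERPINE2 -1.29). Cell cycle genes had a median of 0.00 and a mean of -0.02. None of these members passed, over all genes or adjusted over the list alone.

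In limma 0 genes passed and 24 had an unadjusted p under 0.05, with 63 genes at least 2-fold higher and 88 at least 2-fold lower by size. Without hairpin 2 and with pooled controls, limma called 2652 genes, 1394 higher and 1258 lower, with OSMR at -1.85 (adjusted p = 8.8e-06). The median standard error was 0.484 with hairpin 2 in the fit, since the spread then comes from the hairpins, which differ by 2-fold or more in 2869 genes.

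With Lnc-BM shRNA and no OSM, the hairpins shared few differences from control shRNA. MALAT1 was lower with both hairpins, and NEURL1, which encodes a ubiquitin ligase, was higher, but both also moved that way in JAK2 KO. Hairpin 2 alone stood far from the other 4 arrays, with lower levels of the replication genes RRM2 and TYMS, the cyclin CCNA2 and the cytokines IL6 and CXCL1, and higher levels of the sterol genes INSIG1 and IDI1.

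MALAT1 differed by -1.28 (7.81 with hairpin 1 and 8.09 with hairpin 2 against 9.23) and was as low in JAK2 KO (7.81 against 9.30 in JAK2 WT). CELF2 differed by -1.65, NTSR1 by -1.35, TAF5L by -1.17 and PGC by -1.11. NEURL1 differed by 2.36, PRSS36 by 1.59, KRTAP19-2 by 1.28, MED18 by 1.03, ATF3 by 0.89, YJEFN3 by 0.78, EMILIN1 by 0.77, ACTB by 0.75 and SLC16A12 by 0.72. With hairpins 1 and 2 apart, NEURL1 stood at 1.22 and 3.49, PRSS36 at 0.73 and 2.46, and CELF2 at -1.08 and -2.22. The JAK2 KO array, on slide 2 with hairpin 1, moved alike in several of these genes. Without hairpin 2 and with pooled controls it stood at 1.07 for NEURL1, 0.73 for PRSS36, 0.71 for ATF3 and 0.58 for KRTAP19-2, but at -0.08 for MED18. Slide and hairpin 1 cannot be told apart for them. NTSR1 came to -0.81 and ACTB to 0.42 without hairpin 2 and with pooled controls. For these genes hairpin 1 alone lay close to the mean of both hairpins against control shRNA. The shift therefore comes from adding JAK2 WT to the controls and not from hairpin 2. With hairpin 1 other probes read differently, from -1.29 to 0.14 for TAF5L, from -1.11 to 0.14 for PGC and from -0.03 to 0.74 for ACTB. They ranged from -0.11 to 0.65 for ATF3 and from 0.88 to 2.35 for MED18. CFAP157, CELA3A and PLA2G2E were not above background with either hairpin and were at least 3.85-fold, at least 2.52-fold and at least 2.09-fold higher with control shRNA, whereas MPP7, dim with control shRNA, was at least 1.73-fold higher with the hairpins. CFAP157 was dim in JAK2 WT as well (5.94 against 8.14 with control shRNA), and CELA3A and PLA2G2E were dim on every array but control shRNA. OSMR was 6.65 with hairpin 1 and 8.56 with hairpin 2 against 8.89. JAK2 differed by 0.09, STAT3 by 0.13, IL6ST by 0.20, LIFR by 0.65, SOCS3 by -0.22, ICAM1 by -1.02 and CCL2 by -1.58. The last 4 rest on hairpin 2 for most of their size: with hairpins 1 and 2 LIFR stood at -0.01 and 1.32, SOCS3 at 0.17 and -0.61, ICAM1 at 0.16 and -2.19, and CCL2 at -0.40 and -2.76.

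All 40 cell cycle genes had a mean level below control shRNA (median -1.07), which came to -0.12 with hairpin 1 and -2.02 with hairpin 2. RRM2 stood at 13.02 with hairpin 1, 7.70 with hairpin 2 and 12.99 with control shRNA, and CCNA2 at 12.63, 9.24 and 12.74. Chemokines and cytokines had a median of 0.06 with hairpin 1 and -1.17 with hairpin 2 (CXCL1 15.45 and 10.69 against 15.61, IL6 12.54 and 7.54 against 12.21). NF-kB targets had medians of 0.02 and -1.09, EMT and matrix remodelling genes 0.04 and -0.70, and cholesterol synthesis genes -0.04 and 0.58. In the immediate early list the median of the mean difference was -0.16 and its mean 0.01. No member passed, over all genes or adjusted over the list alone.

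In limma 0 genes passed and 16 had an unadjusted p under 0.05, with 5 genes at least 2-fold higher and 13 lower with both hairpins. Hairpin 1 alone differed by 2-fold in 21 genes upward and 26 downward, hairpin 2 alone in 1298 and 1566. Without hairpin 2 and with pooled controls, OSMR differed by -2.15 on the single hairpin 1 array. The spread of that fit, and of the same fit without hairpin 1, is that between the control arrays of slide 1 alone. It holds nothing of the spread between slides.

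**Figure D3:**
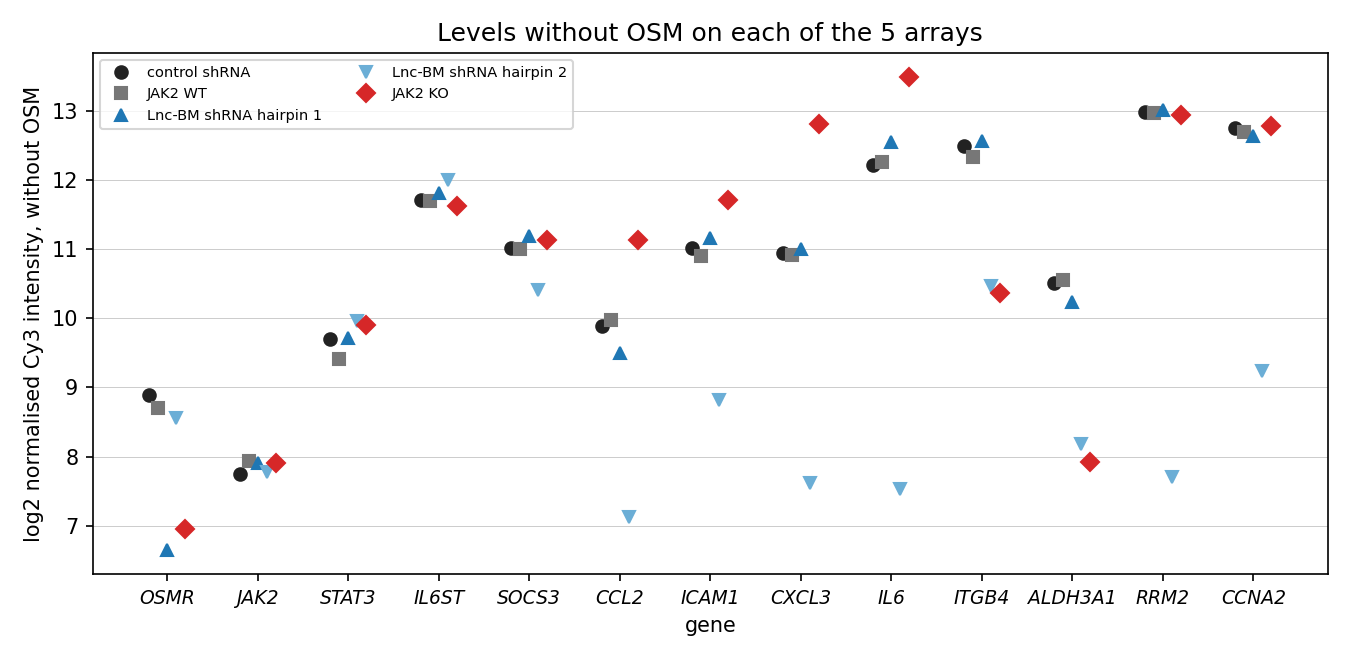
Log2 Cy3 level of 13 genes without OSM on each of the 5 arrays. Genes were chosen among those named in the text.

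Levels after OSM were compared last. JAK2 KO lay lower than JAK2 WT in 27 of 29 JAK-STAT3 targets (median -0.46), 25 of 30 hypoxia and glycolysis genes (median -0.25) and 18 of 24 adhesion molecules (median -0.22). Chemokines and cytokines went both ways (median 0.02), with IL32 at 1.33 and IL11 at 1.21 but CXCL5 at -1.07 and IL6 at -0.78. DHRS3 (1.91) and CXCR4 (1.20) were higher in JAK2 KO, with most of the DHRS3 difference already there without OSM. With hairpins 1 and 2, NF-kB targets had medians of -0.22 and -1.13, interferon-stimulated genes -0.32 and -0.40 and acute phase proteins -0.17 and -0.31, and the array of hairpin 2 stood apart before OSM too. In limma 0 genes passed for JAK2 KO and 0 for Lnc-BM shRNA, with 31 and 39 at an unadjusted p under 0.05. By size, 51 genes were higher and 113 lower by 2-fold in JAK2 KO, and 3 higher and 47 lower with both hairpins. Without hairpin 2 and with pooled controls, SOCS3 with OSM differed by -1.56 in JAK2 KO and by -1.44 with hairpin 1. The spread of that fit is that between the control arrays of slide 1 alone.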

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

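The opposite directions of UBE2E1 (chromosome 3, 23930634 to 23930693, build hg19), a gene for a ubiquitin-conjugating enzyme, stood out. Its OSM ratio was -1.51 with control shRNA and -1.48 in JAK2 WT, was 0.11 with hairpin 1 and 0.84 with hairpin 2, and lay further down, at -2.21, in JAK2 KO. Against their controls the hairpins differed by 1.62 and 2.35 and JAK2 KO by -0.72, and the Lnc-BM effect minus the JAK2 effect came to 2.71 (standard error 0.45). It was picked because its ratio moved 1 way with every hairpin and the other way in JAK2 KO. The untreated level was 9.17 with control shRNA, 6.79 with hairpin 1 and 8.18 with hairpin 2, so the hairpins' higher ratios come with a lower untreated level, whereas JAK2 WT and JAK2 KO had 9.11 and 9.20. The level with OSM did not show the same opposition. Without hairpin 2 and with pooled controls it differed by -0.74 with hairpin 1 and by -0.65 in JAK2 KO, while hairpin 2 lay above control shRNA. The sizes asked for (2-fold with each hairpin, 1.5-fold in JAK2 KO) were set after the values were seen. In the main fit the limma test of the difference gave an adjusted p of 1.00. With scan session as a block, which equals leaving out hairpin 2 with pooled controls, the difference was 2.32. The test result depends on this choice of fit. The spread of the blocked fit is that between the control arrays of slide 1 alone, so it does not settle the call.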

How the results depend on the processing

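Most values kept their direction and their side of the test: of gene values under the alternatives, 686 of 917 for the OSM response in the controls, 409 of 569 and 420 of 558 for its change with Lnc-BM shRNA and in JAK2 KO, and 507 of 592 and 457 of 565 for levels without OSM. In the controls 215 lost the call, 16 gained it and 0 reversed. The main fit called 0 genes in the other comparisons, so keeping the side there means staying uncalled, and no call could be lost. In the same order, 154, 133, 65 and 99 values gained a call there. For the controls and JAK2 KO, leaving out either hairpin and scan session as a block are the same fit, counted each time. Of list medians 507 stayed, 52 moved and 8 reversed. The number of arrays, the shared slide of the controls and the dim signals, 57.4 percent of Cy3 features well above background on the hairpin 2 array, limit every call. No paired analysis was possible because the groups share no numbers that pair their samples. A joint fit of both dyes and slide as a random block were not run, since their correlations could not be estimated, and the authors' table gives no levels. Except where named, the cause was not tested.

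The count of OSM calls in the controls, 838, became 0 with the scanner's processed signals and with the authors' table (2957 and 2870 genes at an unadjusted p under 0.05), 167 with an offset of 16, 195 with a variance trend, 319 with all spots in the background model (chosen after seeing the data), 520 with the strict filter, which tests fewer genes, 2551 with pooled controls and 5890 without either hairpin or with scan session as a block. With median centring it was 565, split 248 higher and 317 lower against 513 and 325. Pooled controls gave 61 calls for Lnc-BM and 25 for JAK2, and median centring 53, 11 and, for the difference of effects, 1. Leaving out a hairpin, with pooled controls, gave 697 to 3009 calls for Lnc-BM, 656 for JAK2, and 164 to 1243 for their difference. For levels without OSM it gave 458 to 11799 and 2652, and with OSM 1937 to 12654 and 4087. By construction the spread is then that between the control arrays of slide 1. Scan session as a block equals leaving out hairpin 2, with 697, 656, 164, 458, 2652, 1937 and 4087 calls.

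Genes at 2-fold or more in the OSM ratio of control shRNA, hairpin 1, hairpin 2, JAK2 WT and JAK2 KO numbered 143, 23, 72, 135 and 19. They became 582, 358, 946, 640 and 343 with processed signals and 518, 350, 826, 576 and 288 with the authors' table. At 1.5-fold, a lower bar by construction, they were 478, 150, 393, 483 and 83. Hairpin 1 had 36 without background correction and 40 with an offset of 16, hairpin 2 had 184 with median centring, and control shRNA 73 with all spots. Differences of 2-fold in the OSM response were 186 for Lnc-BM and 510 for JAK2 with processed signals, 174 and 475 with the authors' table, 133 and 255 at 1.5-fold, and for Lnc-BM 44 with an offset of 16, 18 with median centring, 8 with all spots and 38 to 195 when a hairpin was left out. In levels without OSM they were 288 and 1109 with processed signals, 50 and 245 with an offset of 16 and 100 and 952 at 1.5-fold. For Lnc-BM alone they were 36 without background correction, 29 without a filter, 7 with the strict filter, 11 with the mean of probes and 47 to 2864 when a hairpin was left out. In levels with OSM they were 369 and 837, 92 and 278, and 231 and 886 under the first 3 of these settings, and for Lnc-BM 33 with the strict filter and 80 to 2639 when a hairpin was left out. The correlation of the effects, 0.485, was 0.292 with processed signals, 0.289 with the authors' table, 0.338 with median centring and 0.317 with all spots. With all spots hairpin 1 kept 60.8 percent of the response and hairpin 2 kept 26.5.

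Some single genes that changed sign lay near 0, but ITGB3 in the OSM response and ICAM1, IL6, CXCL2, RRM2 and CDC25A without OSM did not. For the Lnc-BM effect on the OSM response IL6ST was 0.31 with median centring, 0.00731 with the mean of probes, 0.0489 with pooled controls and -0.155 to 0.25 when a hairpin was left out, LIFR was 0.0622 with median centring and ITGB3 0.0262 with all spots. For the JAK2 effect IL6ST was -0.15 with the mean of probes and -0.0274 with pooled controls, without either hairpin and with session as a block. In levels without OSM, the Lnc-BM difference of JAK2 was -0.00904 with processed signals, -0.0170 with median centring, -0.50 with all spots, -0.00516 with pooled controls and -0.0743 to 0.0640 when a hairpin was left out, and that of STAT3 -0.0216 with median centring. Without hairpin 2 (the same with session as a block) and without hairpin 1 it was -0.0119 and 1.32 for LIFR, 0.18 and -0.60 for SOCS3, 0.21 and -2.13 for ICAM1, 0.30 and -4.70 for IL6, 0.0709 and -4.29 for CXCL2, 0.0403 and -5.28 for RRM2, and 0.0398 and -3.46 for CDC25A, which by construction is each hairpin alone. The JAK2 KO difference of LIFR was -0.0132 and of SOCS3 -0.0405 with processed signals. That of JAK2 was 0.0110 with all spots, 0.0446 with median centring between arrays and 0.0573 with pooled controls, without either hairpin and with session as a block, and that of IL6ST 0.00468 with median centring between arrays. List medians of the Lnc-BM effect on the OSM response turned to 0.0749 (interferon), 0.0420 (NF-kB), 0.24 (immediate early), 0.21 (EMT), 0.21 (hypoxia) and 0.18 (cholesterol) with median centring, and to 0.00551 (chemokines) with all spots. The fibroblast and basal median of the JAK2 effect was 0.0637 with the strict filter.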

Other observations

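Some genes had an OSM ratio on the same side of 0 on every array, JAK2 KO included. The choice was made after the values were seen: 27 genes were at least 1.5-fold higher on all 5 arrays and 2, DMBT1 and IL11, at least 1.5-fold lower. Among the 27 are SERPINB3, NNMT and SOCS3, whose ratios were much smaller on the perturbed arrays. Closer in size across arrays were genes of metallothioneins, small proteins that bind zinc and copper, and of the zinc exporter SLC30A1, though less so with hairpin 2. MT2A stood at 1.39 with control shRNA, 1.33 in JAK2 WT, 1.18 with hairpin 1, 1.67 with hairpin 2 and 1.22 in JAK2 KO, MT1X at 0.84, 0.89, 0.79, 0.74 and 0.82, and SLC30A1 at 1.40, 1.33, 1.02, 0.80 and 1.72, in the same order. Their sequences are much alike, so the metallothionein probes are not independent readings. CYP1B1, a cytochrome P450 gene, was alike too (1.35, 1.25, 1.22, 1.36 and 1.15). Lower in JAK2 KO than elsewhere, but by little, were SLC7A11, a cystine transporter gene (0.91, 0.87, 0.93, 1.05 and 0.66), and HMOX1, the gene of haem oxygenase 1 (0.90, 0.89, 0.70, 1.14 and 0.60). Of 143 genes at 2-fold or more with control shRNA, 11 kept 80 percent or more of the JAK2 WT ratio in JAK2 KO: RPL23, UBE2E1, SLC30A1, MT1M, MT1E, CYP1B1, MT2A, VEGFA, EGR1, MT1A and MALAT1. RPL23 had a ratio of only 0.42 in JAK2 WT against 1.01 with control shRNA, and another of its probes a control mean of 0.11. Probes of VEGFA differed by -0.08 and -0.58 between JAK2 KO and JAK2 WT. Without a dye swap, a probe's dye bias in these ratios has no test here.

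Other genes differed between the Lnc-BM and JAK2 effects on the OSM response, none past the limma test of the difference. PATL1 (1.38), RNF121 (1.21) and TAF5L (1.16) had the Lnc-BM effect above the JAK2 effect, and EGR1 (-1.17), RNA28SN5 (-0.92) and SLC30A1 (-0.88) below it. These were also chosen after their values were seen. Without hairpin 2 and with pooled controls, where the spread is that of the slide 1 controls alone, the difference was 1.14 for TAF5L and -1.06 for EGR1.

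The tests below of bright genes, of the neighbours of the OSMR spot and of GC content were written before their values were known (the bright-gene test after the share kept by all genes was), and the other 6 were chosen only after the result was seen.

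Genes at 2-fold or more on the controls had smaller OSM ratios on the JAK2 KO and both hairpin arrays, although hairpin 2 had more genes 1.5-fold higher (343) than control shRNA (308). An offset that flattens dim genes is argued against for JAK2 KO by 32 bright genes, which kept a median of 38.5 percent (49.7 with hairpin 1 over 29 genes), but stays open for part of the loss with hairpin 2, at 42.0 over bright genes against 15.5 over all. The ribosomal protein list did not shrink, with a median of 0.30 in JAK2 KO and 0.25 in JAK2 WT. It cannot decide on a factor that shrinks every ratio. Without a dye swap, a fixed dye bias could hold the ratio of this list alike on every array. A lower OSMR level is argued against for hairpin 2, whose OSMR differed from control shRNA by only -0.34. It stays open for hairpin 1 and JAK2 KO, where OSMR was lower, as does slide, since 0 slides hold an array with its control and slide and the loss of JAK2 or Lnc-BM cannot be told apart.

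Without OSM, OSMR was lower on the hairpin 1 and JAK2 KO arrays (6.65 and 6.95 against 8.89 and 8.71). A fault of the slide around that spot is argued against by 39 neighbouring probes, whose median difference was -0.0362 with hairpin 1. These arrays share slide 2, and 4 genes were lower by 2-fold on both against 0.126 if independent, so slide and perturbation cannot be told apart for OSMR.

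The hairpin 2 array stood apart from the others without OSM. GC content of the probes, with a correlation of -0.140 to the difference, is argued against, and so are scanner and software alone, which would not single out cell cycle genes (median -2.02). Hairpin 1 had -0.12 for the same list, and whether the rest comes from hairpin 2 itself or from its culture and session cannot be told apart.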
